A study of Halobacterium salinarum NRC-1 with 28 samples.

How the data were processed

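The samples were total RNA of Halobacterium salinarum NRC-1 at 7 times of growth, 2 cultures per time and 2 arrays per culture with exchanged dyes. Per the labels, cultures grew in shaken flasks (220 RPM) at 37 degrees C, RNA was extracted with a column kit, and 10 micrograms of sample and of reference RNA were hybridised to arrays with 4 spots per 70-mer oligonucleotide for 2400 genes. Per the labels, the dyes were Alexa 546 and Alexa 647, and the dye of the sample is stated for each array. The labels describe the reference RNA as mid-log RNA at OD600 0.5 to 0.6 in one place and as RNA of the final time point of another experiment in another place. The array design, scanner and image software are not given in the sources used here.

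Per the file headers, each deposited scanner file holds spot and background intensity for both dyes at a brighter and a dimmer scan, not background-corrected and not normalized, with the pixel spread, the pixel number and a confidence value per spot, of which the last serves as a filter. The deposited value table holds log10 ratios that the authors made from the raw data, per the labels, with a maximum likelihood step whose details are not given in the sources used here. Setting it against the scanner values showed log10 of Alexa 546 over Alexa 647 whichever dye the sample had, with a correlation between 0.843 and 0.9961 (median 0.9836) and a slope between 0.766 and 1.05 per array when spots were read slide row by slide row, and at most 0.195 in size when read in spot number order. The column medians lay between -0.0612 and 0.145, and 0 to 1714 values per column were exactly 0. Its centring and the handling of the zeros stayed unknown.

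Log2 ratios were computed from the brighter scan with means over pixels, a choice made after the files were seen, as was the spot set definition. Background was corrected with normexp (offset 50) and each array normalized by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Control spots could not be told apart here, so none had weight 0. Ratios were turned to sample over reference by the labelled dye, averaged over the 4 spots of a set and over the 2 arrays of a culture, and the 14 culture means were tested. The 2688 spot sets comprise 10752 spots, and 532 spots carried 1 gene symbol, 0 several and 10220 none. Of the 133 named genes, all 133 symbols and none of the Entrez identifiers matched the RefSeq table, which is of another strain of the species, so it served for names only, and no coordinates are given.

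limma was fitted to all cultures with time point as factor, 7 residual degrees of freedom and no block, with Benjamini-Hochberg adjusted p under 0.05. Before the data were examined, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed. The named genes are the 12 largest rises and 12 largest falls between 540 and 3120 min that passed and whose cultures did not overlap, 3 and 3 for each step, the 5 largest ranges for the F-test, up to 2 rises and 2 falls of each list, and fixed genes where measured. The rule was applied among named genes, and at most 2 unnamed spot sets per direction were added. Lists were tested with limma's camera (preset correlation 0.01, two-sided), 31 lists having been fixed and 10 having at least 4 measured members. Members were matched by gene symbol alone, so a list can miss a member or hold a gene of another function.

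A spot set counted as above background on an array where at least 3 of its 4 spots had a foreground over background by more than 3 standard errors, and as saturated at 65000 or more. Where a set was above background on none of the 4 arrays of a time, only a lower bound of the fold is given. It is from the sample channel after loess and equalised mean intensities, against the lowest signal among sets above background. Where the set's own mean signal was higher than that, as for rpmC at 3120 min, the bound was taken against that mean. It then equals the change in the sample channel. Such bounds use the sample channel alone and can exceed a fold from the ratio. The adjusted p beside a bound tests the ratio, whose fold is also given for some sets where the bound exceeds it. The share of sets above background in the sample channel ranged from 24.6% to 68.9% per array, and 2 to 15 sets were saturated. csg was saturated on all arrays of 540 and 3120 min and has no fold.

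The replicate number is a name given by runs of array numbers and pairs no cultures. At 2760 min both cultures had the same optical density, so arrays were tied to cultures by array number, and the crossed pairing is an alternative. Alternatives changed the background correction, normalization, spot summary, dim and low-confidence filters, dye orientation, treatment of technical arrays, samples in the fit and source of values, and left out each culture in turn. Added after the data were seen were the turned sign of the 1260 min culture at OD600 0.830, also with a replicate block, the dimmer scan, medians over pixels and the sample channel alone. The sample channel alone was read by the labelled dyes. On both arrays of the 1260 min culture at OD600 0.830 that channel lay closer to the reference profile than the other channel.

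The procedure was tested on simulated data with 200 of 2688 spot sets changed and 20 draws. For 540 against 3120 min with the noise as labelled, 17.6%, 65.4% and 93.9% of changes of log2 0.5, 1 and 2 were recovered, with 5.46% false among the calls. With the noise after turning the sign these were 60.6%, 96.6% and 100%, with 5.7% false. The simulation gave all cultures independent normal noise with 1 SD per spot set. In the data as labelled, the SD of the difference between paired cultures was 0.963 at 1260 min. It was 0.134 at 540 min and 0.241 at 3120 min, so the simulated rates as labelled need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9.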

Results

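Transcript levels of Halobacterium salinarum NRC-1, an archaeon that lives in nearly saturated salt, were followed over growth in shaken complete medium at 37 degrees C. Cultures were sampled at 7 times, 540, 890, 1260, 1860, 2280, 2760 and 3120 min, with 2 cultures per time, so that 14 cultures were measured. Each culture was hybridised on 2 arrays with the dyes exchanged, against a common reference RNA, which gave 28 arrays. The labels speak of duplicate flasks but do not say whether the same flasks were sampled at every time. The optical density (OD600) of the paired cultures was 0.225 and 0.220 at 540 min, 0.496 and 0.468 at 890 min, and 0.807 and 0.830 at 1260 min. It was 0.758 and 0.733 at 1860 min, 0.781 and 0.764 at 2280 min, 0.913 in both cultures at 2760 min, and 1.023 and 1.086 at 3120 min. Of 2688 spot sets per array, 133 had a gene name in the tables used here and 2555 had none. The share of spot sets above background in the sample channel averaged 61.1% at 540 min, 52.4% at 1860 min and 34.2% at 3120 min, over 4 arrays each. The number of cultures, 2 per time, limits the precision of every value.

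**Figure D1:**
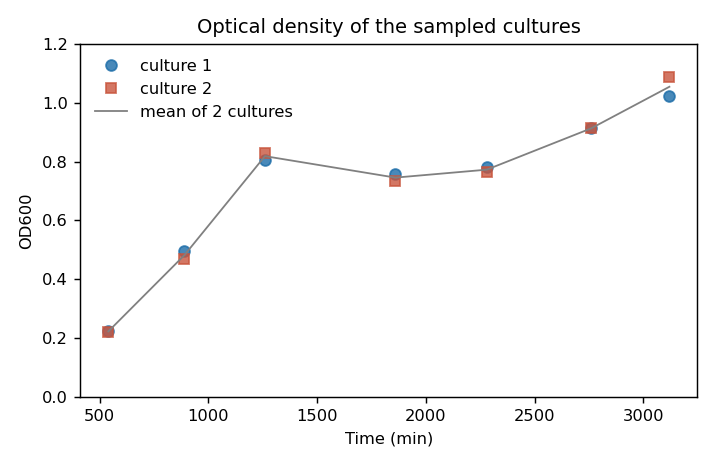
Optical density OD600 (y axis) against time in minutes (x axis) for the 2 cultures of each time point, with a line through their means. The density rose from 0.225 and 0.220 at 540 min to 0.807 and 0.830 at 1260 min, and reached 1.023 and 1.086 at 3120 min.

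The log2 ratios of paired cultures had correlations across spot sets between 0.85 and 0.95 at 6 of the 7 times. At 1260 min the correlation was -0.89 as the dyes were labelled, and 0.89 after the sign of the culture at OD600 0.830 was turned. The correlation of that culture with the 13 others ranged from -0.89 to -0.48. Both of its arrays ran against their labelled dye. On both, the channel labelled reference lay farther from the reference profile of the other arrays than the channel labelled sample, by 0.328 and 0.347 in SD, against -0.568 to -0.0537 on the 26 other arrays. The labelled dyes were kept, and the counts of every comparison are given with the sign of this culture turned too. As labelled, the 1260 min means average 2 cultures whose ratios ran in opposite directions (r = -0.89). As-labelled changes to and from that time mix them. The median residual SD per spot set was 0.216 as labelled and 0.134 with the sign turned. The plot of culture 2 against culture 1 shows the opposite slopes at 1260 and 1860 min.

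**Figure D2:**
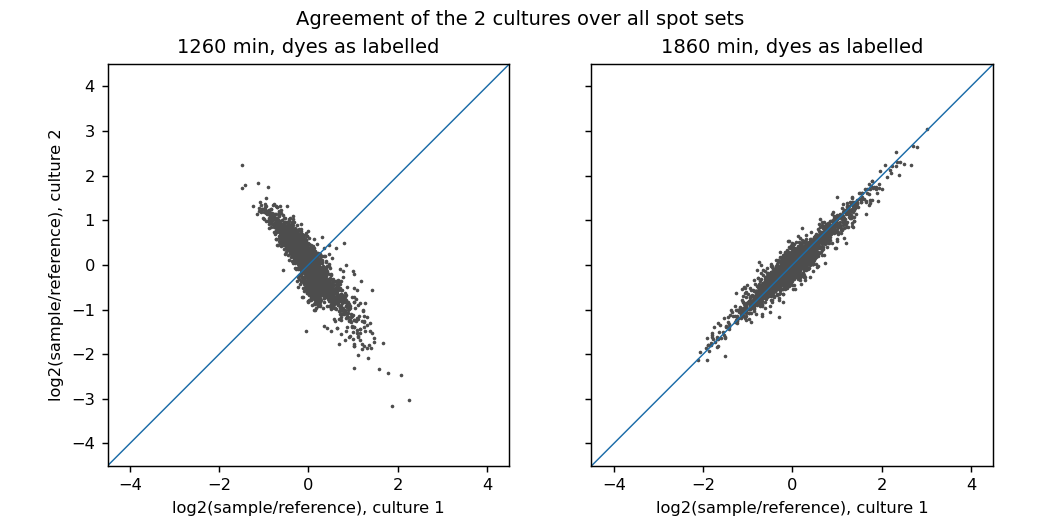
Log2 ratio of sample over reference in culture 2 (y axis) against culture 1 (x axis) at 1260 min (left) and 1860 min (right), dyes as labelled, 1 point per spot set, with the line of equal values. The correlation was -0.89 at 1260 min and 0.95 at 1860 min.

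After loess and equalised mean intensities, the signal of the reference channel was not constant. From 540 to 3120 min its change had a slope of 0.39 on the change of the sample channel (r = 0.82 across spot sets, which are not independent replicates). The same slope was 0.30 when the reference signal came from culture 1 and the sample signal from culture 2, and 0.36 the other way. The SD over spot sets of the change was 0.922 in the sample channel and 0.436 in the reference channel. Values from the sample channel alone are given beside the ratio for some genes.

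The first against the last time point asked which transcripts differ between early growth and the densest cultures. Among the named genes that passed, the ribosomal protein genes rpl12p and rpmC were lower at the end. The transducer genes htr7, htr8 and htr18 were higher and the transducer gene htr4 was lower. rpl12p, a protein of the ribosomal stalk, decreased by 1.94 ± 0.41 (log2, SE, n = 2 cultures per time; limma adjusted p = 0.01), and rpmC, a protein of the large ribosomal subunit, was at least 4.08-fold lower at 3120 min (adjusted p = 0.014). Of the genes of carbon metabolism, some also fell: the succinyl-CoA ligase subunits sucC and sucD changed by -1.63 ± 0.17 and -1.54 ± 0.15 (adjusted p = 0.00021 and 0.00018), malate dehydrogenase mdh by -1.19 ± 0.19 (adjusted p = 0.003), enolase eno by -1.05 ± 0.31 (adjusted p = 0.044) and phosphoenolpyruvate synthase ppsA by -1.03 ± 0.27 (adjusted p = 0.031), while citZ, icd and tpiA did not pass (adjusted p = 0.8, 0.16 and 0.11). The glutamate dehydrogenase gene gdhA1 fell by 1.83 ± 0.15 (adjusted p = 6.8e-05) while gdhB rose by 1.0 ± 0.25 (adjusted p = 0.024), and glutamine synthetase glnA changed by -1.02 ± 0.19 (adjusted p = 0.0055). The cobalamin genes cobN and cbiT changed by -1.49 ± 0.24 and -1.23 ± 0.28 (adjusted p = 0.0027 and 0.016), and the lysyl-tRNA synthetase lysS by -1.10 ± 0.33 (adjusted p = 0.046). cbiT and lysS were above background on 1 of 4 arrays at 3120 min.

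Among the genes that rose was argH, argininosuccinate lyase, which makes arginine. It gained 2.22 ± 0.60 (adjusted p = 0.033), and was above background on 1 of 4 arrays at 540 min. The phosphoserine phosphatase serB rose by 1.17 ± 0.28 (adjusted p = 0.021) and aroC, chorismate synthase, by 0.47 ± 0.13 (adjusted p = 0.038). The methionine sulfoxide reductase msrA rose by 1.06 ± 0.19 (adjusted p = 0.0043) and the ferritin-like DNA-binding protein dpsA by 0.96 ± 0.29 (adjusted p = 0.045). The taxis transducers htr8 and htr7 gained 1.04 ± 0.14 and 0.87 ± 0.14 (adjusted p = 0.0011 and 0.003). By the bound from the sample channel, the transducer htr18 was at least 3.33-fold higher at 3120 min, and bat, the activator of bacteriorhodopsin genes, at least 2.85-fold. In the ratio htr18 was 2.27-fold and bat 2.17-fold higher (adjusted p = 0.008 and 0.0043). hutG passed the test (adjusted p = 0.024) but was not well above background at either time, so no fold is given. Of unnamed spot sets, row2115 was at least 66.3-fold higher by the bound from the sample channel and 11.1-fold higher in the ratio (adjusted p = 0.00089). The unnamed row1605 rose by 3.41 ± 0.57 (adjusted p = 0.0034), while row2875 and row3133 changed by -2.49 ± 0.20 and -2.14 ± 0.36 (adjusted p = 6.8e-05 and 0.0034). In the sample channel alone, argH rose by 3.76, gdhB by 1.78 and dpsA by 1.44. Values no larger in size than the ratio included rpl12p at -1.80, gdhA1 at -1.73, sucC at -1.54, cobN at -1.34 and htr7 at 0.84, while hutG, and aroC at 0.50, did not pass (adjusted p = 0.093 and 0.057).

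In all, 437 of 2688 spot sets changed between 540 and 3120 min, 221 upwards and 216 downwards, 30 of them named (11 up, 19 down). The count with the sign turned was 1367 (653 up, 714 down), of which 436 were shared in direction with the 437. The contrast itself does not contain the 1260 min cultures, which enter only through the spread, and without either of them the count was 1473. Without replicate 1 or 2 of 540 min the count was 120 or 138, and without replicate 1 or 2 of 3120 min it was 207 or 145. The split of directions moved with the scaling: 226 rose and 348 fell after median centring without loess, and 920 rose and 238 fell in the authors' values, where the median change of all spot sets was 0.30. Of the 30 named genes called, 27 were refitted without each culture in turn, and of these 7 kept the call when any 1 of the 14 cultures was left out: htr8, htr7, gdhA1, sucC, sucD, cobN and mdh. The calls of argH, dpsA, aroC, lysS and eno were each kept in 2 of 14 such fits, with adjusted p up to 0.23, the fits without a 1260 min culture being the ones that kept them. The call of aroC was also lost after median centring, at 0.23 (adjusted p = 0.22). All fits without 1 culture kept the dyes as labelled. With all cultures and the sign turned, argH, dpsA, lysS and eno had SEs of 0.12, 0.10, 0.11 and 0.11. Their limma adjusted p was then 6e-08, 7.9e-06, 3.7e-06 and 6.1e-06.

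**Figure D3:**
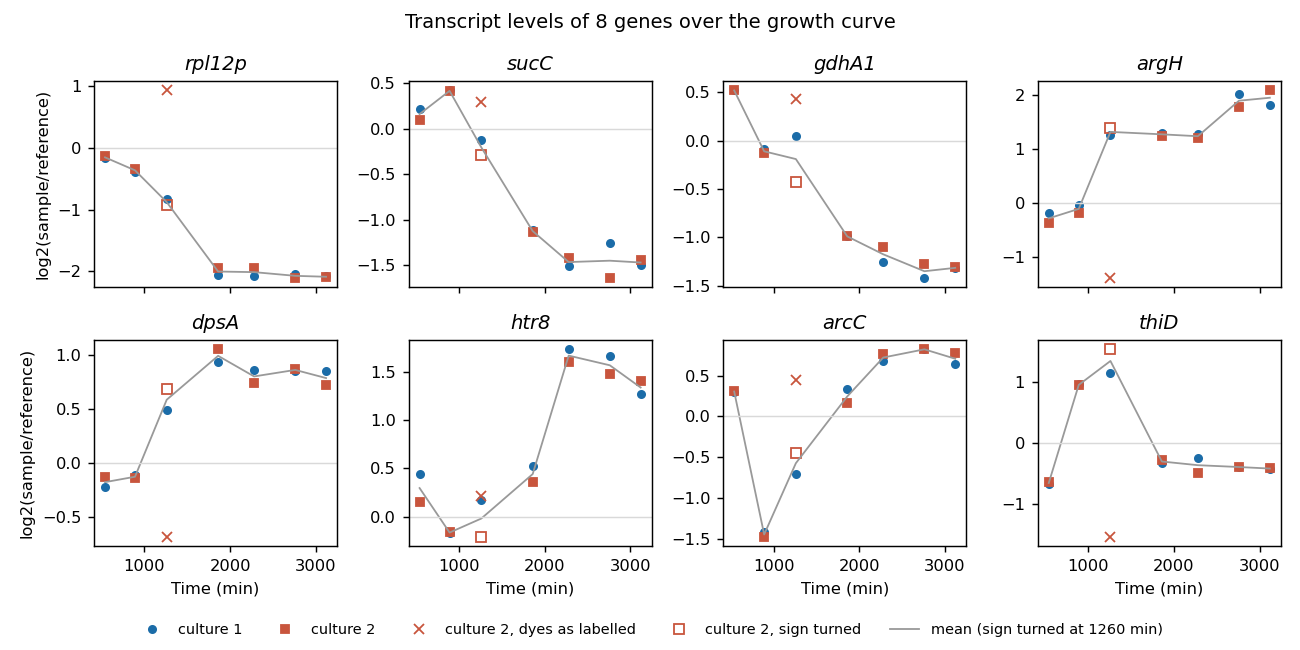
Log2 ratio of sample over reference (y axis) against time in minutes (x axis) for rpl12p, sucC, gdhA1, argH, dpsA, htr8, arcC and thiD in each culture, with a line through the means after the sign of culture 2 at 1260 min was turned. Crosses give culture 2 at 1260 min as its dyes were labelled and open squares give it turned. rpl12p was at -2.00 at 1860 min and -2.09 at 3120 min, and htr8 went from 0.44 at 1860 min to 1.66 at 2280 min.

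The gene lists fixed for this comparison asked whether whole pathways moved between 540 and 3120 min. Of 10 lists with at least 4 measured members, 4 moved by limma's camera test with a preset correlation of 0.01. The tricarboxylic acid cycle fell (adjusted p = 0.00062; adjusted p = 0.045 with an estimated correlation). Of its 6 measured members, sucC, sucD, mdh and the succinate dehydrogenase subunit sdhC fell, sdhC by 0.50 ± 0.11 (adjusted p = 0.017). In the sample channel alone sdhC was at -0.29 and did not pass (adjusted p = 0.23). The isocitrate dehydrogenase icd and the citrate synthase citZ did not pass, at -0.29 ± 0.13 and -0.05 ± 0.13. Adjusted over the list alone, the same number, 4, passed. In the turned reading 5 of the 6 fell.

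The 14 aminoacyl-tRNA synthetases and related amidotransferases, which charge tRNAs, fell as a list (adjusted p = 0.002; adjusted p = 0.41 with an estimated correlation). lysS and serS fell, serS by 0.90 ± 0.16 (adjusted p = 0.0043, above background on 1 of 4 arrays at 3120 min), 12 members did not pass, and 4 passed when adjusted over the list alone. In the turned reading 10 of the 14 fell. The list of 4 cobalamin genes moved downwards (adjusted p = 0.022; adjusted p = 0.3 with an estimated correlation), cobN and cbiT having passed and cbiQ and cbiG being at -0.29 ± 0.13 and -0.22 ± 0.15. Adjusted over the list alone, 2 fell. In the turned reading 3 of the 4 fell.

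The 11 chemotaxis genes rose as a list (adjusted p = 0.027; adjusted p = 0.48 with an estimated correlation). htr18, htr8 and htr7 rose and the transducer htr4 was at least 1.19-fold lower (adjusted p = 0.0072; 0.19 in the authors' values), while 7 members did not pass, among them cheA at 0.57 ± 0.34, cheY at 0.58 ± 0.35 and htr2 at 0.02 ± 0.16. htr1 and htr6, at 0.80 and 0.73, passed in the sample channel alone, at 0.98 and 1.15 (adjusted p = 0.006 and 0.0046). The counts adjusted over the list alone were 3 up and 1 down. In the turned reading 9 rose and 1 fell. The list's adjusted p was 0.28 after median centring, 0.68 in the authors' values and 0.063 without replicate 1 of 3120 min.

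The other 6 tested lists did not pass the list test. The list of bacteriorhodopsin and retinal genes (list test, adjusted p = 0.18) had 4 measured members, bat, hop, sop1 and sop2. The bacteriorhodopsin gene itself and genes of retinal or carotenoid synthesis were not among them. Of the 4 members, 1 rose, bat, and 2 passed adjusted over the list alone. With the sign turned 3 rose. The sensory rhodopsin genes sop1 and sop2 were at 0.80 ± 0.28 and -0.26 ± 0.17, and halorhodopsin hop at 0.58 ± 0.25. Amino acid synthesis (16 members; adjusted p = 0.37) held 4 genes that rose (argH, serB, gdhB, aroC) and 3 that fell (gdhA1, glnA and the histidine gene hisB), with the same counts adjusted over the list alone. With the sign turned 4 rose and 9 fell. Purine and pyrimidine synthesis (12 members; adjusted p = 0.39) had no member past the limma test over all spot sets and 0 adjusted over the list alone. That held as the dyes were labelled, and with the sign turned 2 members rose and 4 fell. purF and purE were at 0.45 ± 0.49 and 0.32 ± 0.37, and purL at -0.69 ± 0.41. DNA replication (adjusted p = 0.47), DNA repair (adjusted p = 0.88) and the proteasome (adjusted p = 0.88), with 4 members each, had 0 members past the test and 0 adjusted over the list alone. With the sign turned 1 DNA replication gene fell, and in the proteasome list 1 rose and 1 fell. The gene panB entered the proteasome list by its symbol alone, so that list may hold a gene of another function. The extremes of these lists as labelled included orc7 at 0.16 ± 0.29, gyrB at -0.41 ± 0.19, gyrA at -0.38 ± 0.17, psmA at 0.43 ± 0.15 and panB, which was above background on 4 of 4 arrays at 540 min and on none at 3120 min. In the sample channel alone sop1 and psmA passed upwards, at 1.27 and 0.96 (adjusted p = 0.00083 and 0.0053). gyrB, gyrA and purL passed downwards there, at -1.05, -1.20 and -1.02 (adjusted p = 0.0093, 0.00044 and 0.012), and gyrA passed after median centring too, at -0.53 (adjusted p = 0.034). pyrF and the repair gene radB also passed downwards in the sample channel alone (adjusted p = 0.0068 and 0.023). Both were above background on 4 of 4 arrays at 540 min and on none at 3120 min, so these changes are not sized. radB passed upwards in the authors' values (adjusted p = 0.035), so its direction stays open. The proteasome list had a median of 0.00, a mean of -0.01 and a test direction upwards. The same 4 lists moved with the sign turned and none held with an estimated correlation (lowest adjusted p = 0.097).

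Another 10 lists had 1 to 3 measured members and were not tested as lists. Ribosomal proteins held rpl12p, and oxidative stress defence held dpsA and msrA, all of which passed. The symbol pattern of the ribosomal list did not match rpmC, which also passed. dpsA was also the 1 member of the list for iron and other metals. Glycolysis and gluconeogenesis held eno and ppsA, which fell, and tpiA, which was above background on 4 of 4 arrays at 540 min and on none at 3120 min. The respiratory chain held sdhC, which fell, and nuoL at -0.31 ± 0.15. nuoL passed at -0.85 after median centring, -0.67 in the authors' values and -0.63 in the sample channel alone (adjusted p = 0.032, 0.029 and 0.014). The chaperone dnaK fell by 0.57 ± 0.14 (adjusted p = 0.021) and dnaJ was at 0.00 ± 0.26. The arginine fermentation genes arcA and arcC were at 0.47 ± 0.14 (adjusted p = 0.052) and 0.39 ± 0.28. Their values moved with the scaling, to 0.02 and -0.11 in the authors' values and to -0.01 and -0.17 after median centring. The translation factor infB, the glycerol kinase glpK and the phosphate gene phoU were at -0.76 ± 0.44, -0.50 ± 0.23 and 0.63 ± 0.28, none past the test, though all 3 passed in the sample channel alone, at -0.94, -1.13 and 0.91 (adjusted p = 0.0059, 0.0051 and 0.0085). The remaining 11 lists, among them gas vesicle, archaellum, ATP synthase and transposase genes, had no named member.

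The same lists were also tested for each step, as description. From 540 to 890 min the lists of purine and pyrimidine synthesis and of cobalamin synthesis moved upwards (adjusted p = 0.018 for both; adjusted p = 0.51 and 0.46 with an estimated correlation). From 1260 to 1860 min the chemotaxis list and the list of bat, hop, sop1 and sop2 moved upwards (camera adjusted p = 0.0059 and 0.033). With an estimated correlation the camera adjusted p was 0.44 for both. The tricarboxylic acid cycle and aminoacyl-tRNA synthetase lists moved downwards at that step (adjusted p = 0.0062 and 0.016; adjusted p = 0.13 and 0.44 with an estimated correlation). From 2280 to 2760 min the cobalamin list moved downwards (adjusted p = 0.0078; adjusted p = 0.27 with an estimated correlation). After the sign was turned, the cobalamin list from 540 to 890 min and the aminoacyl-tRNA synthetase list from 1260 to 1860 min did not pass (adjusted p = 0.065 and 0.2). Passing then were the aminoacyl-tRNA synthetase list downwards from 890 to 1260 min, and the proteasome and purine and pyrimidine lists downwards from 1260 to 1860 min (adjusted p = 0.038, 0.0067 and 0.00026; adjusted p = 0.27, 0.093 and 0.12 with an estimated correlation). Of the turned step calls, the tricarboxylic acid cycle from 1260 to 1860 min held (adjusted p = 0.043 with an estimated correlation).

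From 540 to 890 min the arginine fermentation genes arcA and arcC fell as the dyes were labelled. The arginine deiminase arcA changed by -1.10 ± 0.14 (adjusted p = 0.014) and the carbamate kinase arcC by -1.75 ± 0.28 (adjusted p = 0.035). carB, the large subunit of carbamoyl phosphate synthase, which feeds pyrimidine and arginine synthesis, rose by 2.25 ± 0.36 (adjusted p = 0.035) and was above background on 1 of 4 arrays at 540 min. limma called 7 spot sets, 2 up and 5 down. With the sign turned it called 57 (34 up, 23 down), and the thiamine synthesis genes thiD and thiC then rose by 1.59 ± 0.12 and 1.19 ± 0.19 (adjusted p = 1.2e-05 and 0.0066), gdhA1 fell by 0.63 ± 0.13 (adjusted p = 0.028) and pan1, a proteasome-activating ATPase, was at least 2.10-fold higher (adjusted p = 0.014). In the sample channel alone thiC rose by 4.11, carB by 3.42 and thiD by 3.18. After median centring arcA, arcC and carB kept values of -1.14, -1.73 and 2.21 but did not pass (adjusted p = 0.062, 0.28 and 0.068), and in the authors' values arcC, at -1.71, and carB, at 1.76, did not (adjusted p = 0.19 and 0.084). Without either 1260 min culture the count was 77, without any 1 culture of 540 or 890 min it was 0, and without 1 of a later time than 1260 min it was 4 or 5. arcA kept its call in 10 of 14 such fits, and carB and arcC in 2.

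From 890 to 1260 min no spot set passed limma's test as the dyes were labelled, with 255 at unadjusted p under 0.05. Turning the sign gave 719 (358 up, 361 down). argH then rose by 1.42 ± 0.12 (adjusted p = 2.1e-05) and arcC and arcA by 0.87 ± 0.11 and 0.82 ± 0.12 (adjusted p = 2e-04 and 0.00051), while carB, lysS and hisF changed by -0.94 ± 0.20, -0.77 ± 0.11 and -0.69 ± 0.15 (adjusted p = 0.0046, 0.00037 and 0.0051). The count was 312 without the culture at OD600 0.830 and 1698 without the other, where argH took the opposite sign at -1.27.

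From 1260 to 1860 min the ribosomal protein genes rpl12p and rpmC fell and bat and dpsA rose, by less when the sign was turned. rpl12p fell by 2.05 ± 0.41 (adjusted p = 0.018), rpmC by 1.94 ± 0.47 (adjusted p = 0.04) and gdhA1 by 1.24 ± 0.15 (adjusted p = 0.0013). bat rose by 1.2 ± 0.20 (adjusted p = 0.006) and dpsA by 1.08 ± 0.29 (adjusted p = 0.047), and htr18 was at least 1.5-fold higher (adjusted p = 0.014). Turned, rpl12p was at -1.12 ± 0.09, rpmC at -0.82 ± 0.16, gdhA1 at -0.80 ± 0.13 and dpsA at 0.40 ± 0.10 (adjusted p = 5.4e-06, 0.0033, 0.0014 and 0.016), and htr18 was at least 1.16-fold higher (adjusted p = 0.015). In the sample channel alone, with the dyes as labelled and not turned, rpl12p was at -0.95. limma called 235 spot sets (139 up, 96 down), and 431 with the sign turned (219 up, 212 down), 206 of them shared. With only the cultures of these times in the fit, dyes as labelled, limma called 0, with 135 at unadjusted p under 0.05. The genes that the turned sign puts first were bat at 0.87 ± 0.11, arcC at 0.82 ± 0.11, thiD at -1.64 ± 0.12, carB, at least 1.95-fold lower, and pan1, at least 7.19-fold lower (adjusted p = 0.00019, 0.00021, 3.8e-06, 0.0012 and 2e-04). The bound for pan1 is from the sample channel, and in the ratio pan1 was 2.2-fold lower. The count was 357 without the culture at OD600 0.830 and 1965 without the other, 29 or 48 without replicate 1 or 2 of 1860 min, and between 99 and 116 without any 1 culture of another time. Of the 15 named genes called, the 6 given above were refitted without each culture in turn, and of these gdhA1 kept its call in every fit.

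From 1860 to 2280 min the transducer htr8 rose by 1.22 ± 0.14 (adjusted p = 0.017). The unnamed row3033 was at least 3.80-fold higher by the bound from the sample channel and 2.95-fold higher in the ratio (adjusted p = 0.041). htr8 and row3033 were the 2 spot sets that limma called. Turning the sign gave 186 (92 up, 94 down), among them htr18 at 0.73 ± 0.17 and arcA at 0.62 ± 0.12 upwards (adjusted p = 0.026 and 0.0098), and hisG, ppsA and cobN at -0.57 ± 0.16, -0.52 ± 0.11 and -0.42 ± 0.09 (adjusted p = 0.047, 0.014 and 0.021). Without either 1260 min culture the count was 244, without any 1 culture of 890, 1860 or 2280 min it was 0, and without 1 of 540 or 3120 min it was 1. htr8 kept its call in 8 of 14 such fits.

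From 2280 to 2760 min limma called 0 spot sets, with 68 at unadjusted p under 0.05. With the sign turned it called 6 (3 up, 3 down), of which cobN was the 1 named gene, at -0.59 ± 0.09 (adjusted p = 0.026), and without either 1260 min culture it called 7. From 2760 to 3120 min it called 0 in either reading, with 26 at unadjusted p under 0.05 as labelled and 182 with the sign turned.

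Across all 7 time points 549 spot sets changed by limma's F-test, 36 of them named, and 1622 with the sign turned, 104 of them named. By the ratio as labelled, the named genes with the largest range of time-point means were carB, arcC, rpmC, rpl12p and htr18. arcC spanned 2.27 (adjusted p = 0.0028), from -1.44 ± 0.04 (SD, n = 2) at 890 min to 0.82 ± 0.00 at 2760 min, and rpl12p spanned 2.14 (adjusted p = 0.0053). carB, rpmC and htr18 were below background on all 4 arrays of at least 1 time, so no range is given for them and their rank is uncertain (adjusted p = 0.0067, 0.014 and 0.00087). With the sign turned argH and thiD took the place of rpl12p and htr18, with ranges of 2.22 and 1.98 (adjusted p = 5.1e-08 and 1.4e-07). Without any 1 culture the count ran from 284 to 2220, with 2220 and 1706 without the 1260 min cultures and between 284 and 374 without any 1 culture of another time.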

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

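The 3 tests on the reference channel moving with the sample channel were chosen only after the result was seen. A single group of 4 arrays stood out among the 14 groups of arrays and channels examined for a value far from the others. In the array of replicate 1 at 1260 min with the sample in Alexa 647, 64.6% of spot sets were above background in the sample channel, against 56.1% to 57.2% on the other 3 arrays of that time. Chance marks about 1 in 20 such groups, and the 4 arrays are 2 technical pairs. The pair of the culture at OD600 0.830 is the one that ran against its labelled dyes. Its channels labelled reference had 57.3% and 27.9% of spot sets above background, so the flag depends on the labels.

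Both arrays of the 1260 min culture at OD600 0.830 ran against their labelled dye. On each, the channel labelled reference lay farther from the reference profile of the other arrays than the channel labelled sample, by 0.328 and 0.347 in SD, while on the other 26 arrays this difference lay between -0.568 and -0.0537. That argues against RNA that differs from the reference in the opposite direction, and an exchange of the dye labels of both arrays is a candidate explanation. An exchange of the dye columns in the files is argued against by the slopes on the probe-specific dye bias, 0.701 and 1.38. No biological explanation beyond the opposite RNA was tested.

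The labels describe the common reference in different ways. RNA like that of the 3120 min cultures here is argued against by the SD over spot sets of the ratio to the reference at 3120 min, 0.634 and 0.673 in the paired cultures, above the 0.306 and 0.307 at 890 min. The label names the final time point of another experiment, whose density is not given in the sources used here. That reading therefore stays open, and both descriptions could hold together. Mid-log RNA stays open too, since the SD was lowest at 540 min in both cultures and so the test at 890 min did not decide. No biological explanation was tested.

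The reference channel moved with the sample channel from 540 to 3120 min, with a slope of 0.39. A single change of reference RNA between the arrays of 890 and 1860 min is argued against by slopes across cultures of 0.30 over 540 to 890 min and 0.28 over 1860 to 2280 min. Hybridisation differing for both channels alike is argued against as the whole cause by correlations of 0.51 and 0.44 across cultures between the reference channel's change and the ratio's change. Signal of the sample reaching the reference channel may account for it, since those slopes were above 0.2. A reference prepared separately for each time was not tested and would leave the same trace. Both channels were taken after loess and equalised mean intensities, which can tie the channels of an array together. That processing was not tested as a cause, so the slopes do not single out any of these. No biological explanation was tested. The slopes were 0.098 and 0.014 over 2280 to 2760 min and -0.16 and -0.19 over 2760 to 3120 min, where the sample channel's own changes in the paired cultures had correlations across spot sets of 0.24 and -0.23, so these steps decide nothing.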

How the results depend on the processing

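Chosen only after the results were seen were the turned sign of replicate 2 at 1260 min (also with the replicate block), the dimmer scan, the medians over pixels and the sample channel alone, and every other alternative here was planned. Values are counts of changed spot sets, and the cause was not tested unless stated. Only counts that moved beyond a set ratio from the main count, or to or from 0, are given. A count that was made and is not given stayed within that ratio or at 0. Without background correction the counts were 10 for 890 to 1260 min, 359 for 1260 to 1860 min and 4 for 1860 to 2280 min. Median centring gave 565 for 1260 to 1860 min and 1 for 1860 to 2280 min. Loess with scaling between arrays gave 24, 44, 94 and 0 for the first 4 steps. The median over spots gave 1 for 1860 to 2280 min. The authors' values gave 1103 over all times, 1158 for 540 to 3120 min and 1 for 1860 to 2280 min. Arrays with the sample in Alexa 546 gave 130 for 1260 to 1860 min and 0 for 1860 to 2280 min, and those in Alexa 647 gave 4 for 540 to 890 min, 138 for 1260 to 1860 min and 0 for 1860 to 2280 min. Arrays as observations gave 1012 over all times and 14, 24, 761 and 21 for the first 4 steps. The replicate block gave 1 for 1860 to 2280 min, the crossed pairing at 2760 min 6 and leaving out the array numbered apart 7. With only the compared times in the fit, 1399 passed for 540 to 3120 min, 96 for 540 to 890 min, 0 for 1260 to 1860 min and 104 for 1860 to 2280 min. The turned sign gave 1622 over all times, 1367 for 540 to 3120 min and 57, 719, 431, 186 and 6 for the first 5 steps, and with the replicate block 1642, 1362, 56, 710, 430, 191 and 5. The dimmer scan gave 13, 20, 92 and 34 for the first 4 steps, and medians over pixels 4 for 1860 to 2280 min. The sample channel alone, by the labelled dyes, gave 1255 over all times and 1155 for 540 to 3120 min. By step it gave 20 for 540 to 890 min, 73 for 890 to 1260 min, 59 for 1860 to 2280 min and 4 for 2280 to 2760 min. With an estimated correlation 1 list moved.

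Leaving out 1 culture at a time, with the lone culture assumed to vary like the others, gave 284 to 2220 over all times, 120 to 1473 for 540 to 3120 min, 0 to 77, 0 to 1698, 29 to 1965, 0 to 244, 0 to 7 and 0 to 0 for the 6 steps, and 3 to 4 lists. The range for the lists comes only from the fits without a culture of 540 or 3120 min. Lists were not retested without a culture of another time. Of single genes and lists, 2622 values stayed on their side of the threshold (of those past it in neither fit, some changed sign), 216 passed newly, 252 no longer passed and 10 reversed. The reversals without replicate 1 at 1260 min were argH at -1.27 and lysS at 0.67 for 890 to 1260 min and thiD at 1.23 for 1260 to 1860 min, against 1.35, -0.70 and -1.45 without replicate 2. hisF for 890 to 1260 min was at -0.69 with the turned sign, with or without the replicate block. pan1 for 1260 to 1860 min was at -0.85 without replicate 2 at 1260 min and 2.11 without replicate 1. It was at -1.14 with the turned sign, with or without the block, and at -2.21 in the sample channel alone. pan1 was above background on none of the 4 arrays at 1860 min, so these values do not size its change. The bound with the turned sign was at least 7.19-fold lower. radB for 540 to 3120 min was at 0.32 in the authors' values. radB was above background on none of the 4 arrays at 3120 min, so that value does not size its change and the direction stays open. Except for radB and the sample channel, each of these reversals came from removing or turning a 1260 min culture. The share of spot sets above background, 34.2% in the sample channel at 3120 min, limits which falls can be sized.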

Other observations

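The observations below were chosen after the data were seen, and no test of an explanation was made for them. When the sign of the 1260 min culture at OD600 0.830 was turned, thiD and purL, picked after their values were seen, had their highest level at 1260 min. thiD, of thiamine synthesis, was at -0.65 at 540 min, 0.95 at 890 min, 1.34 at 1260 min and -0.30 at 1860 min (limma F-test, adjusted p = 1.4e-07 with the sign turned and 0.39 as labelled). purL, of purine synthesis, was at -0.08, 0.60, 0.84 and -0.05 at the same times (adjusted p = 5.4e-06 with the sign turned and 0.12 as labelled), and was above background on none of the 4 arrays at 2760 min.

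The arginine fermentation genes had their lowest level at 890 min, and as labelled no later step was past the test for either. arcA was at 0.26 at 540 min, -0.85 at 890 min, 0.16 at 1860 min and 0.78 at 2280 min (adjusted p = 0.00026 as labelled), and arcC at 0.31, -1.44, 0.24 and 0.72 (adjusted p = 0.0028). argH, of arginine synthesis, was at -0.28, -0.11, 1.27 and 1.24 at those times. Of the measured glutamate dehydrogenase genes, gdhA1 and gdhB changed in opposite directions and gdhA2, at -0.70 ± 0.44, passed from 540 to 3120 min with the sign turned but not as labelled (adjusted p = 0.00048 and 0.28). gdhA1 went from 0.52 at 540 min to -1.31 at 3120 min and gdhB from -0.23 to 0.78, each relative to its own reference signal, and hybridisation of either transcript to the other's oligonucleotide was not tested.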
